A study of Mus musculus with 8 samples.

How the data were processed

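Expression was measured in 8 mouse RNA samples, 4 on an Agilent 1-colour array with Cy3 label and 4 on an Affymetrix gene array, with 1 array per group. Total RNA was extracted with Trizol, per the labels' protocols. Groups were taken from the labels' source names and titles. Affymetrix values were deposited as log2 expression summarised with RMA, per the submitters' processing notes, without a version. RMA corrects background, normalises by quantiles and summarises the probes of a set. The array medians were 3.20 for ES, 3.06 for astrocytes, 3.07 for Bmi1 uninduced and 3.19 for Bmi1 spheres, and a few values lay below 0, so a further step by the authors cannot be excluded.

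The Agilent scanner files hold spot intensity, and per the file headers they were extracted with Agilent Feature Extraction 10.7.3.1 for ES, PM2i-iPSC and OM2i-iPSC and 9.5.3.1 for MEF. The MEF header lists spatial and multiplicative detrending of the signal, and for the other 3 arrays these settings are not given in the sources used here. The 75th percentiles of the processed signal differ between arrays, so it was scaled here. The deposited series table held the same intensity rounded to 3 significant digits, within 0.5% on every spot, with medians of 414, 165, 493 and 522 for ES, MEF, PM2i-iPSC and OM2i-iPSC. It was neither centred nor on a log scale, and it served as an alternative. Coordinates, sequences and gene names came from the MEF file, whose header names grid build mm7 (mm8 for the others). Exon and UTR positions were not analysed here.

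Control spots and flagged outliers were left out, spots of a probe were averaged, and log2 of the processed signal minus the 75th percentile of the array was taken. The percentile was 3160.1 for ES, 1877 for MEF, 3531 for PM2i-iPSC and 3461 for OM2i-iPSC. Of 41174 probes, 23553 were named through their accession, 6289 by symbol and 2953 by an older symbol in the RefSeq table given, and 8379 kept the name in the file. A gene was represented by its brightest probe, which left 27556 genes. Of these, 8881 had several probes, and the disagreements between probes that are stated in the text are not a full list. A gene entered a comparison when it was well above background on at least 1 of the arrays compared. Where the dimmer side was not well above background, the fold was computed against the higher of its own signal and the lowest signal well above background on that array, and is given as "at least". The same wording marks a saturated brighter side, and no fold is given below 1 or where both sides were saturated. The lowest signals were 90.1 in ES, 16.3 in MEF, 147 in PM2i-iPSC and 142 in OM2i-iPSC.

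Genes were counted at 2-fold and 4-fold. With 1 array per group there was no test, no p-value and no replicate error. The precision that can be given is the spread between spots of a probe within an array, with an SD of 0.139 on the log2 scale, or 0.197 for a difference. The 31 gene lists were fixed before the data were examined. For each list the median difference over its members with a fold or a bound is given with a distribution-free 95% interval over its genes and with its percentile among 10000 random lists of the same size, matched in 10 bins of mean expression. Genes are not independent replicates, so both describe these arrays. Shares nearer to ES have 95% Wilson intervals, which cover counting only. Intervals of chromosome medians, mixing shares, percents of the MEF level and the checks of sterol genes are percentile bootstraps of 2000 draws. They resample genes, probes or probe sets as if independent, and those of chromosomes hold the autosomal median fixed.

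The genes named were set by a rule fixed in advance. It took 14 anchor genes, the 6 highest and 6 lowest measured genes of a comparison, up to 4 members with the widest difference and up to 2 opposite members of each list, the 6 genes with the widest difference between ES and MEF among those nearer to MEF in both iPSC preparations, and up to 6 genes per direction that differed from ES the same way in both, ranked by the smaller difference. Outside the anchors and the lists, genes with only a bound and names of clones or predicted genes were left out of these rankings. Values of Mirg, Meg3 and Rian outside their list's comparisons, and the probes of Y-linked genes, were chosen after their values were seen. Affymetrix probe sets entered when the higher value exceeded 3.13, the median over the 4 arrays. No table used here pairs those probe sets with genes, so the planned list medians of that platform were not computed and at most 2 probe sets per direction are named. The planned normexp correction uses a mean signal that 3 of the 4 files do not hold, so it was run on median signals. That alternative, the single detection floor and the share of Affymetrix probe sets nearer to ES were added after the files were seen, and correlations took all genes or probe sets, not only those that enter a comparison as planned. Some genes that the naming rule picked are not reported here, and the counts of alternatives leave them out.

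The alternatives were quantile normalisation, scaling on probes above background on all arrays, the deposited series table, the filters on dim genes, the mean over a gene's probes, normexp with an offset of 50, a single detection floor, and other filters and centring for Affymetrix. The method was tested on simulated data for PM2i-iPSC against ES with 200 genes changed: 2.83-fold and 8-fold increases were called in 100% of 50 genes each, 2.83-fold decreases in 98%, and 1.41-fold increases in 2%. Only the spread between spots was added, and the changed genes lay above the detection floor. Array, slide, preparation and probe error were left out, so these shares do not measure sensitivity on real arrays. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9.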

Results

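Total RNA of 8 mouse cell populations was measured on expression arrays, with 1 array per group. A 1-colour Agilent array was hybridised for each of 4 populations. They were embryonic stem (ES) cells, mouse embryonic fibroblasts (MEF), and induced pluripotent stem cell preparations from MEF treated with combinations that contained purmorphamine (PM2i-iPSC) or an oxysterol (OM2i-iPSC), followed by 2i/LIF. Purmorphamine is a small-molecule agonist of the Hedgehog pathway component Smoothened, certain oxysterols also activate Smoothened, and 2i/LIF is a culture medium with inhibitors of MEK and GSK3 plus the cytokine LIF. An Affymetrix array was hybridised for each of 4 further populations: ES cells, embryonic astrocytes, astrocytes transduced with Bmi1 (called uninduced in the labels), and spheres that formed from such cells under neural stem cell culture (Bmi1 spheres). Bmi1 is a subunit of Polycomb repressive complex 1. The title of the series gives its question as whether small molecules can bring somatic cells to pluripotency. With no replicates, no difference below was tested, and each describes these arrays.

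On the Agilent arrays, 66.9% of the spots lay well above background for ES, 72.8% for MEF, 63.4% for PM2i-iPSC and 66.3% for OM2i-iPSC. ES and PM2i-iPSC shared slide 1. OM2i-iPSC was on slide 2 and MEF on slide 3, which was scanned on another day and read with an older software version, so slide and group cannot be told apart for comparisons with MEF or OM2i-iPSC. Spots of the same probe within an array differed with an SD of 0.10 to 0.17 on the log2 scale.

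The ES and MEF arrays bracket the change from a somatic to a pluripotent cell. Of 21712 genes above background on at least 1 of them, 7318 were at least 2-fold higher and 4872 at least 2-fold lower in ES than in MEF. The pluripotency regulators Pou5f1 (1272-fold), Esrrb (1311-fold), Sall4 (at least 1661-fold), Nanog (at least 297-fold) and Sox2 (16.3-fold) were higher in ES. As log2 relative to the 75th percentile, Pou5f1 and Sall4 read -6.66 and -6.43 in MEF, near that array's floor of -6.85. The size of their folds over MEF, here and below, is therefore uncertain. Klf4 and Myc, which fibroblasts also express, differed by 1.24-fold and 1.35-fold, both lower in ES, and the other 2 probes of Myc had log2 differences of -1.66 and -1.51. Of 31 pluripotency genes with a fold, 29 were at least 2-fold higher and none lower (median log2 difference 5.20, 95% interval 3.44 to 8.58, percentile 100 of 10000 random lists matched on expression). The probe of Nanog, on chromosome 6 from 122750894 to 122750953 of build mm7 in the file, has the sequence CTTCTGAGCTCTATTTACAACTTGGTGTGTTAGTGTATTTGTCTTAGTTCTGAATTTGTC. Its signal was saturated on the ES array, so its fold is a lower bound.

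Fibroblast and mesenchymal genes lay on the other side. Of 33 such genes, 31 were at least 2-fold lower in ES than in MEF (median log2 difference -4.08, 95% interval -5.57 to -2.74, percentile 0), with the matrix proteoglycan Dcn 219.8-fold, the collagen cross-linking enzyme Lox 158-fold, the transcription factor Twist2 177-fold and the surface marker Thy1 16.9-fold lower. Cdh11 went the other way on its brightest probe, 2.34-fold higher in ES, while its other probes were lower in ES. TGF-beta response genes (median log2 difference -4.06, 95% interval -4.43 to -0.96, percentile 0) were lower with them, among them Tgfb1 (at least 155-fold), Tgfb2 (229.7-fold) and Tgfb3 (21.6-fold). Interferon response genes were lower in 14 of 17 cases (median log2 difference -2.26, 95% interval -3.87 to -1.39, percentile 0), among them Ifit3 (72.6-fold) and Oasl2 (37.4-fold) and the antigen-presentation subunit B2m, at least 20.9-fold lower. Genes of the Hox clusters were lower in 19 and higher in 3 of 34 (median log2 difference -2.37, 95% interval -4.09 to -0.19, percentile 0), with Hoxd13 (85.6-fold) and Hoxa9 (at least 45.0-fold) at the low end.

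Epithelial genes were at least 2-fold higher in ES in 12 of 18 cases and lower in 3 (median log2 difference 2.33, 95% interval 0.89 to 5.40, percentile 99.9). They included the adhesion molecule Cdh1, at least 386-fold higher, the tight-junction proteins Cldn7 and Cldn6, at least 296-fold and 125-fold higher, and the keratin Krt8, 149-fold higher. Germline and 2-cell-stage genes were higher in 10 of 12 (median log2 difference 5.95, 95% interval 2.53 to 6.65, percentile 100), with Mael (at least 277-fold), Zscan4c (159-fold), Stk31 (at least 100.2-fold) and Hormad1 (at least 90.7-fold). Dazl of that list was 8.73-fold lower on its brightest probe and higher on its other probe. Cell cycle genes were higher in 14 of 25 (median log2 difference 1.24, 95% interval 0.37 to 1.82, percentile 99.9), while cell cycle inhibitors were lower in 6 and higher in 2 of 12 (median log2 difference -1.10, 95% interval -2.04 to 0.40, percentile 1.24). Cdkn2a (log2 difference -4.25), Cdkn2b (9.93-fold) and Cdkn1a (4.11-fold) were lower, and Cdkn2c (4.29-fold) and Cdkn2d (2.30-fold) higher. DNA methylation genes went both ways, with 5 higher and 3 lower of 11 (median log2 difference 0.73, 95% interval -1.48 to 4.45, percentile 73.4). The de novo methyltransferase Dnmt3b was at least 73.3-fold and the dioxygenase Tet1 21.9-fold higher, and Mbd3 3.23-fold lower. Outside the lists, Fam25c (770.3-fold), Mreg (595-fold) and Tex13b (574-fold) were among the 6 highest measured genes in ES under the naming rule, which leaves out bounds. Fam25c and Tex13b were dim in MEF, at -6.02 and -6.20, so the size of their folds is uncertain. Mmp13 (277-fold), Spdef (261-fold) and Mcpt8 (248-fold) were among the 6 lowest.

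**Figure D1:**
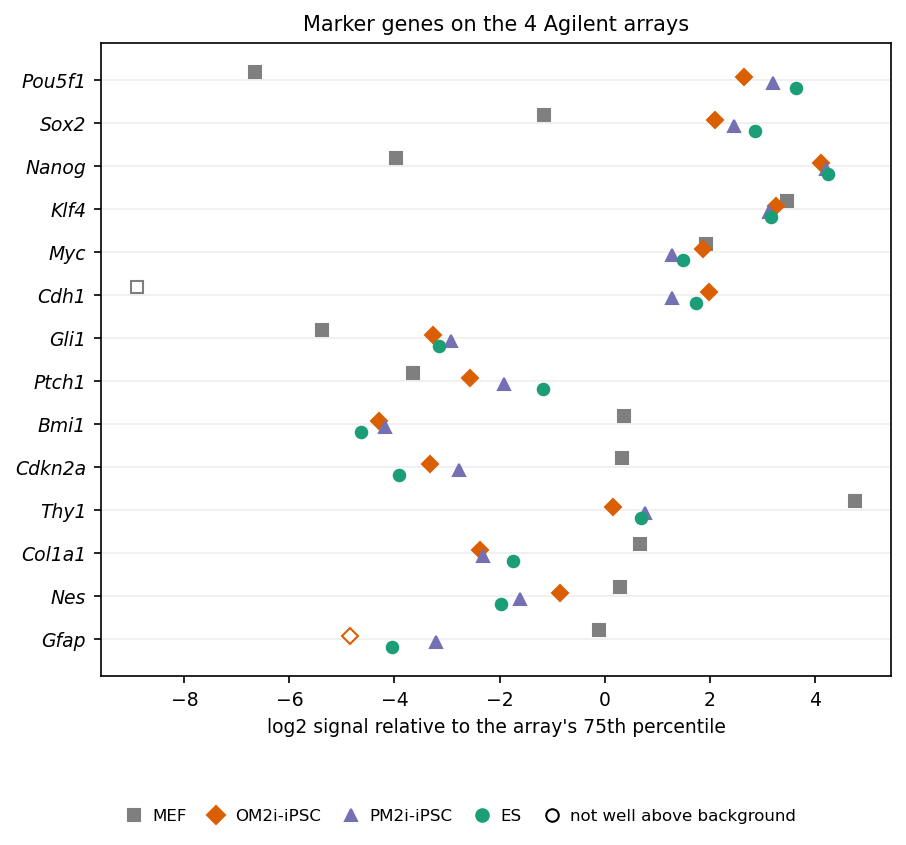
Signal of 14 marker genes on the 4 Agilent arrays, 1 array per group, as log2 relative to the 75th percentile of the array (horizontal axis). Filled symbols were well above background and open ones were not, and Pou5f1, Nanog and Cdh1 of both iPSC preparations lay beside ES and far from MEF.

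PM2i-iPSC were set against MEF, the cell type they were made from, to see which genes differed. Whether the cells on the MEF array were those that were treated is not known here. Of 21690 genes, 7345 were at least 2-fold higher and 5124 at least 2-fold lower in PM2i-iPSC. Pluripotency genes were higher in 28 of 31 (median log2 difference 4.79, 95% interval 3.25 to 8.19, percentile 100), with Pou5f1 (938-fold), Esrrb (at least 1173-fold), Sall4 (at least 1468-fold), Nanog (at least 289-fold) and Sox2 (12.3-fold). Fibroblast genes were lower in 32 of 33 (median log2 difference -4.12, 95% interval -5.46 to -3.28, percentile 0), with Dcn (338-fold), Lox (at least 367-fold), Lum (at least 245-fold) and Thy1 (16.0-fold). Epithelial genes were higher in 12 of 18 (median log2 difference 2.98, 95% interval 0.53 to 4.62, percentile 100), led by Cldn7 (at least 550.0-fold), Cdh1 (at least 280.5-fold) and Cldn6 (157-fold). Germline and 2-cell-stage genes were higher in 11 of 12 (median log2 difference 5.93, 95% interval 2.85 to 6.66, percentile 100), TGF-beta response genes lower in 13 of 15 (median log2 difference -5.02, 95% interval -6.71 to -2.22, percentile 0) and interferon response genes lower in 13 of 18 (median log2 difference -2.41, 95% interval -5.00 to -0.82, percentile 0). The interferon-induced Ifi27 was 332-fold lower, among the 6 lowest measured genes under the naming rule.

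OM2i-iPSC against MEF gave 8007 genes at least 2-fold higher and 5098 at least 2-fold lower, of 21878. Pluripotency genes were higher in 28 of 31 (median log2 difference 5.99, 95% interval 2.71 to 8.08, percentile 100), with Pou5f1 (641-fold), Nr5a2 (at least 857-fold), Esrrb (813-fold), Nanog (at least 271-fold) and Sox2 (9.52-fold). Fibroblast genes were lower in 30 of 33 (median log2 difference -3.55, 95% interval -5.40 to -3.20, percentile 0), with Dcn (at least 506-fold), Twist2 (461-fold), Lum (at least 248-fold) and Thy1 (24.4-fold). Epithelial genes were higher in 14 and lower in 3 of 18 (median log2 difference 2.08, 95% interval 1.36 to 4.99, percentile 99.1), with Cldn7 (at least 1065-fold), Cdh1 (at least 456-fold) and Epcam (40.9-fold). Germline and 2-cell-stage genes were higher in 10 of 12 (median log2 difference 5.67, 95% interval 2.70 to 6.78, percentile 100), and TGF-beta and interferon response genes lower in 13 of 15 and 12 of 18 (median log2 difference -4.33, 95% interval -5.70 to -2.22, percentile 0, and median log2 difference -2.59, 95% interval -4.93 to -0.25, percentile 0). The trophoblast and caudal regulator Cdx2 was at least 141-fold higher in OM2i-iPSC than in MEF, and at least 11.2-fold higher in PM2i-iPSC.

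The Hedgehog list speaks to the pathway that purmorphamine and some oxysterols act on. Its members went both ways relative to MEF on each array: 7 of 17 were at least 2-fold higher and 7 lower in ES (median log2 difference 0.06, 95% interval -2.06 to 2.32, percentile 25.9), 7 and 7 of 16 in PM2i-iPSC (median log2 difference -0.09, 95% interval -2.02 to 2.06, percentile 17.9), and 8 and 8 of 17 in OM2i-iPSC (median log2 difference 0.49, 95% interval -2.03 to 2.20, percentile 35.5). The pathway effector Gli1 was 4.68-fold, 5.47-fold and 4.28-fold higher in ES, PM2i-iPSC and OM2i-iPSC than in MEF, at a dim level on all 4 arrays. Its target and receptor Ptch1 was 5.56-fold, 3.31-fold and 2.13-fold higher on its brightest probe and lower than in MEF on its other probe. Gas1, a Hedgehog co-receptor that fibroblasts express, was 9.60-fold, at least 37.3-fold and 12.6-fold lower. RNA of the cells at the end of the procedure was measured, so these values do not describe the treatment itself.

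Of 5201 genes that differed at least 4-fold between ES and MEF, with all values under the highest detection floor raised to it here and for the positions, 90.3% (95% Wilson interval 89.4 to 91.0%) lay nearer to ES than to MEF on the PM2i-iPSC array and 85.4% (84.4 to 86.3%) on the OM2i-iPSC array. For genes higher in ES the shares were 88.6% and 85.2%, and for genes higher in MEF 92.5% and 85.6%. Nearer to MEF were 506 genes in PM2i-iPSC and 760 in OM2i-iPSC, and 247 in both, and how much of this overlap comes from the shared ES and MEF arrays was not determined. By these positions and the naming rule, the 6 measured genes with the widest difference between ES and MEF were the acrosomal protein gene Acrbp, the calcium-binding Casq2, the kinesin Kif18a, Nsmce3, Olfr360 and Zbtb34. Acrbp was 37.2-fold higher in ES than in MEF, with 2.32-fold higher in PM2i-iPSC and 1.03-fold lower in OM2i-iPSC, where its other probe was higher than in MEF, and Casq2 was 147-fold, 13.2-fold and 12.7-fold higher than in MEF. On values not raised to the floor, Casq2 in both preparations and Kif18a in OM2i-iPSC lay nearer to ES. Their place on the MEF side therefore comes from the raised MEF value. The intervals cover counting only, not the spread between preparations, and both preparations were compared with the same ES and MEF arrays. PM2i-iPSC shared a slide with ES, OM2i-iPSC did not, and MEF was scanned on another day. Nearness to ES and the gap between the preparations therefore cannot be told apart from slide and scan day.

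**Figure D2:**
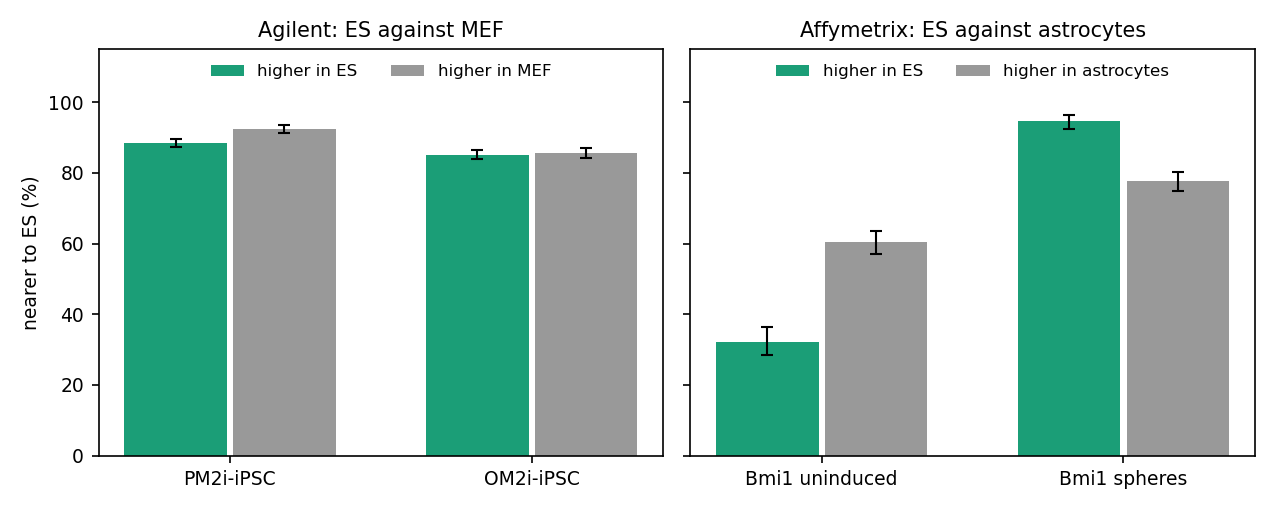
Share of genes (Agilent, left) or probe sets (Affymetrix, right) with at least a 4-fold difference between ES and the somatic array that lay nearer to ES, in percent, split by the array with the higher value. Error bars are 95% Wilson intervals, and the lowest bar is Bmi1 uninduced for probe sets higher in ES, at 32.3%.

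PM2i-iPSC and ES shared a slide, and their arrays had a Pearson correlation of 0.948 across 27556 genes. Of 19880 genes, 2779 were at least 2-fold higher and 2253 at least 2-fold lower in PM2i-iPSC than in ES, and 749 and 449 passed 4-fold. Pluripotency genes were close: 24 of 25 with a fold differed by less than 2-fold (median log2 difference -0.26, 95% interval -0.41 to -0.05, percentile 11.2), with Pou5f1 1.36-fold lower, Sox2 1.33-fold lower and the TGF-beta family member Gdf3, 2.72-fold lower, at the low end. Fibroblast genes were lower in 9 and higher in 2 of 27 (median log2 difference -0.62, 95% interval -1.24 to -0.15, percentile 0.04), with Prrx1 (at least 46.6-fold) and Fbln2 (6.23-fold) lower and Pdgfrb 7.37-fold higher. TGF-beta response genes were lower in 5 and higher in 1 of 14 (median log2 difference -0.71, 95% interval -2.46 to -0.22, percentile 0.2), with Inhba (at least 8.99-fold) and Thbs1 (5.49-fold). Wnt response genes were lower in 4 of 10 and higher in none (median log2 difference -0.61, 95% interval -1.94 to 0.11, percentile 2.83), namely Axin2 (at least 3.94-fold), Sp5 (3.84-fold), Ccnd1 (3.78-fold) and Lef1 (2.89-fold). Imprinted genes were lower in 6 and higher in 1 of 18 (median log2 difference -0.44, 95% interval -1.24 to -0.05, percentile 2.86), with Igf2 (at least 4.87-fold) and Phlda2 (2.76-fold). Astrocyte markers were higher in 5 of 14 (median log2 difference 0.72, 95% interval -0.50 to 1.34, percentile 99.9), among them the glutamate transporter Slc1a2 (6.41-fold) and the lipoprotein Apoe (2.52-fold). Among measured genes under the naming rule, the widest difference upward was Pax2, 57.8-fold higher. Where a gene at least 2-fold apart had another probe, that probe was at least 2-fold the same way in 25.4% of 1117 cases and the opposite way in 11.3%, against 55.0% and 14.5% of 3576 cases for ES and MEF.

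OM2i-iPSC and ES were on different slides of the same scan day, with a correlation of 0.935. Of 20332 genes, 4182 were at least 2-fold higher and 2763 at least 2-fold lower in OM2i-iPSC, and 1219 and 614 passed 4-fold. Pluripotency genes were within 2-fold in 23 of 28, lower in 4 and higher in 1 (median log2 difference -0.66, 95% interval -0.74 to -0.23, percentile 0.05), with Gdf3 (3.98-fold), Tbx3 (at least 2.48-fold) and Tcl1 (2.23-fold) lower, Pou5f1 1.99-fold lower and the germline factor Dppa3 3.61-fold higher. Cell cycle genes were lower in 7 and higher in 1 of 26 (median log2 difference -0.60, 95% interval -0.93 to -0.06, percentile 0.34), with Cdk1 (3.41-fold), Mcm2 (2.62-fold) and Aurkb (2.34-fold). Fibroblast genes were lower in 8 and higher in 4 of 28 (median log2 difference -0.60, 95% interval -0.88 to -0.24, percentile 0.24) and TGF-beta response genes lower in 8 and higher in 3 of 14 (median log2 difference -1.40, 95% interval -2.03 to 1.15, percentile 0), with Inhba (at least 9.08-fold) and Thbs1 (5.17-fold) lower and Tgfb2 (4.43-fold) and Id3 (3.85-fold) higher. Hox genes were higher in 10 of 25 and lower in none (median log2 difference 0.92, 95% interval 0.47 to 1.15, percentile 99.3), among them Hoxd4 (18.5-fold), Hoxd13 (4.62-fold) and Hoxc5 (4.53-fold). Neuronal genes were higher in 6 and lower in 1 of 13 (median log2 difference 0.95, 95% interval 0.36 to 1.78, percentile 97.6), among them the synaptic protein Snap25 (7.32-fold), and oligodendrocyte genes higher in 5 and lower in 1 of 11 (median log2 difference 0.99, 95% interval -0.27 to 2.19, percentile 98), among them Sox10 (4.58-fold) and Mobp (28.1-fold, but a median of 2.80-fold on its other probes). Cdx2 was 11.0-fold higher and the Wnt effector Lef1 7.42-fold higher. The gene's other probe was at least 2-fold the same way in 32.4% and the opposite way in 12.4% of 1735 cases.

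Both preparations were compared with 1 ES array, so their differences share its error. Across 15874 genes the log2 differences from ES correlated with r = 0.505, against 0.50 for simulated preparations without any difference. The same sign was found in 69.1%, against 66.6% simulated. At least 2-fold higher than ES in both were 1231 genes, lower in both 1062 and opposite 248. The covariance of the differences was 0.486, against 0.019 simulated from the spread between spots alone. The simulation leaves out preparation and array error, so how much of the overlap comes from the shared array was not determined. By the naming rule, the genes widest in the same direction were Mxra8, Nsmce3, Stx6, Ephb2, Aspg and Acrbp on the lower side, and Rps6kl1, Pim1, Gna12, Ptprm, Gip and Arap3 on the higher side. Stx6 was 25.5-fold and 27.5-fold lower in PM2i-iPSC and OM2i-iPSC, and the serine kinase Pim1, a LIF-responsive gene, 9.70-fold and 9.43-fold higher. The other probe of Stx6 in PM2i-iPSC, of Acrbp in both, and of Aspg, Pim1 and Arap3 in PM2i-iPSC did not go that way.

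**Figure D3:**
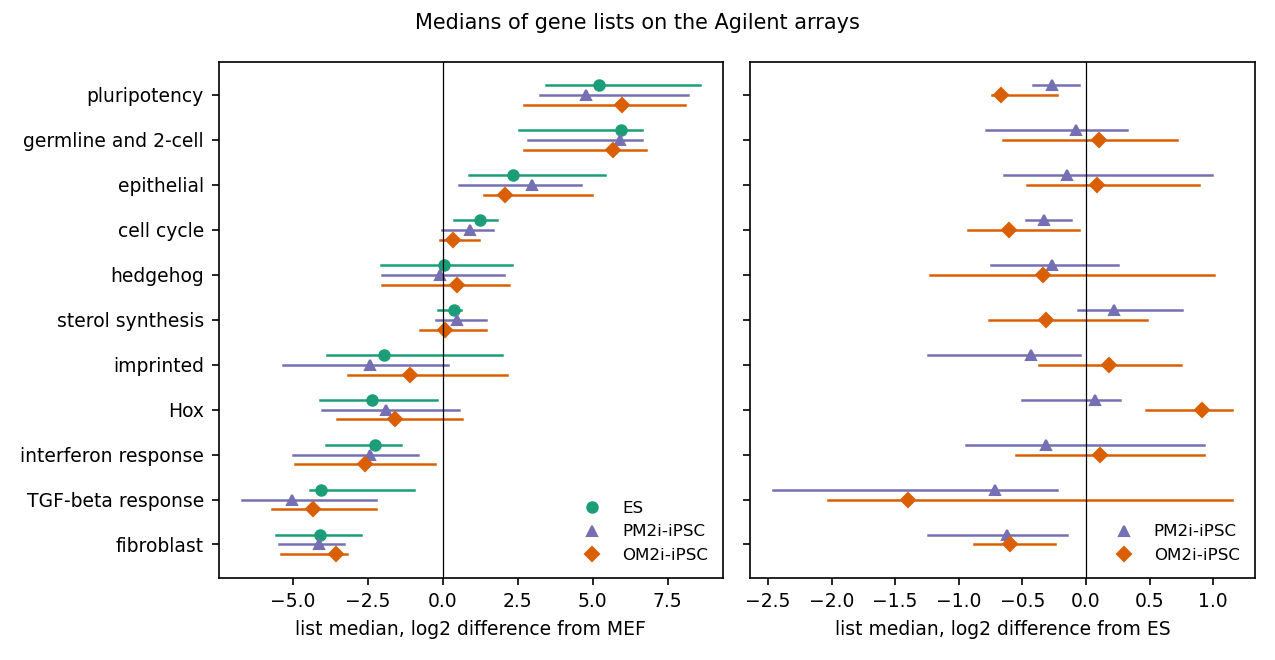
Medians of 11 gene lists on the Agilent arrays, as log2 differences from MEF (left) and from ES (right), with lines for the 95% interval of the median over the genes of a list. The pluripotency median is 5.20, 4.79 and 5.99 above MEF in ES, PM2i-iPSC and OM2i-iPSC, and the fibroblast median is -4.08, -4.12 and -3.55. Relative to ES the pluripotency median is -0.26 in PM2i-iPSC and -0.66 in OM2i-iPSC, and the fibroblast median -0.62 and -0.60. The medians relative to MEF therefore do not rank the arrays.

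PM2i-iPSC and OM2i-iPSC differ by the compound named in their labels and by slide. No dose, time or full combination is given in the labels. Y-linked genes, given below, also set them apart, so compound, slide and starting cells cannot be told apart. Of 20141 genes, 2510 were at least 2-fold higher and 3407 at least 2-fold lower in PM2i-iPSC than in OM2i-iPSC (r = 0.932). Pluripotency genes were within 2-fold in 25 of 27 (median log2 difference 0.29, 95% interval 0.09 to 0.55, percentile 96.1). Sterol synthesis genes were higher in PM2i-iPSC in 8 and lower in 1 of 21 (median log2 difference 0.79, 95% interval 0.02 to 1.33, percentile 100), among them Mvk (log2 difference 1.63), Cyp51 (2.88-fold) and the mevalonate-pathway synthase Hmgcs1 (at least 2.75-fold). The other probe of Mvk was lower in PM2i-iPSC, and over the other probes of 13 sterol synthesis genes the median was only 0.079 (95% interval -0.28 to 1.03). Targets of the liver X receptors, which oxysterols bind, did not move as a list (median log2 difference 0.21, 95% interval -0.69 to 0.71, percentile 81.2), with Lpl 5.31-fold lower and the cholesterol transporter Abca1 2.90-fold higher. Genes responsive to LIF and Stat3 were higher in 1 of 12 and lower in none (median log2 difference 0.56, 95% interval 0.04 to 0.81, percentile 99.3). Hedgehog genes went both ways, with 2 higher and 4 lower of 16 (median log2 difference -0.18, 95% interval -1.51 to 0.88, percentile 50.4), and Gli1 was 1.28-fold higher. The other probe was at least 2-fold the same way in 32.4% and opposite in 12.1% of 1402 genes.

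Imprinted genes were lower in PM2i-iPSC than in OM2i-iPSC in 9 and higher in 2 of 19 (median log2 difference -0.86, 95% interval -1.97 to -0.11, percentile 0.06). The maternally expressed noncoding RNAs of the Dlk1-Dio3 domain stood out, with Mirg (at least 44.7-fold), Rian (at least 26.1-fold) and Meg3 (5.88-fold) lower. All 5 probes of Meg3 were higher in OM2i-iPSC than in ES and PM2i-iPSC. The brightest Meg3 probe, on chromosome 12 from 107092697 to 107092756 in mm7, read 3.01 in MEF, 1.49 in OM2i-iPSC, -0.87 in ES and -1.07 in PM2i-iPSC, as log2 relative to the 75th percentile. Against MEF its probes disagreed, with 2 of the 5 higher in OM2i-iPSC, as was the other probe of Rian. Igf2 was at least 7.82-fold lower in PM2i-iPSC, and the growth inhibitor Cdkn1c 4.80-fold higher. The Y-linked genes Ddx3y (at least 51.2-fold), Eif2s3y (at least 15.3-fold) and Uty (at least 28.0-fold) were lower in PM2i-iPSC, where none was well above background. Endoderm genes were lower in 4 of 7 (median log2 difference -1.35, 95% interval -2.18 to 0.62, percentile 0.96) and trophoblast genes lower in 4 of 7 (median log2 difference -1.08, 95% interval -3.66 to 0.07, percentile 2.03), with Cdx2 (12.6-fold) and Hand1 (3.05-fold). In the Wnt list, Lef1 (21.4-fold), Sp5 (5.05-fold) and Axin2 (at least 4.50-fold) were lower and Dkk1 at least 10.1-fold higher.

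**Figure D4:**
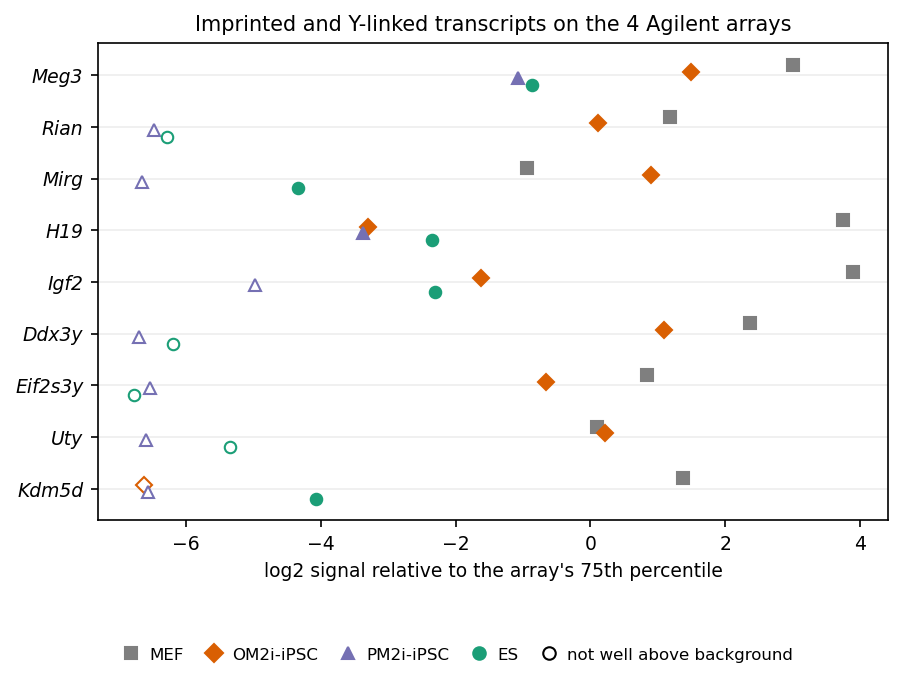
Signal of 5 imprinted and 4 Y-linked transcripts on the 4 Agilent arrays, as log2 relative to the 75th percentile of the array (horizontal axis), with open symbols for genes not well above background. OM2i-iPSC lies well above PM2i-iPSC for Rian, Mirg, Ddx3y, Eif2s3y and Uty, and at the floor with it for Kdm5d.

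Cdkn2a is a known target of repression by Bmi1, so both were read on the Agilent arrays. Cdkn2a was lower in ES, PM2i-iPSC and OM2i-iPSC than in MEF, with log2 differences of -4.25, -3.11 and -3.66. The probes of Bmi1 disagreed: the brightest was 32.1-fold lower in ES than in MEF, and the other was higher in ES, so no direction is given for Bmi1. The Polycomb list, Bmi1 included, was higher in ES in 12 of 21 and lower in 4 (median log2 difference 1.52, 95% interval 0.19 to 3.13, percentile 98.8), with Pcgf2 (270.0-fold) and Cbx7 (64.1-fold) at the top. Pcgf2 read -6.51 in MEF, near the floor there, so the size of its fold is uncertain.

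The Affymetrix arrays followed astrocytes through Bmi1 transduction to spheres, with ES cells beside them. Their 35557 probe sets could not be paired with genes here, so the values describe probe sets, and the transduced Bmi1 could not be checked. Bmi1 uninduced cells differed from astrocytes in 2585 probe sets at least 2-fold higher and 1979 lower, of 18979. The widest differences were at probe sets 10582545 and 10582549, 921-fold and 531-fold higher, and 10603151 and 10355500, 144-fold and 101-fold lower. Bmi1 spheres differed from the uninduced cells in 1526 higher and 1667 lower probe sets, of 19068, with 412 and 154 past 4-fold. Probe sets 10547641 and 10597268 were 232-fold and 231-fold higher in spheres than in uninduced cells, and were 257-fold and 339-fold lower in uninduced cells than in ES.

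Spheres and ES had the highest Pearson correlation of the pairs on this platform, 0.961 across probe sets. Spheres and uninduced cells were close behind, at 0.954. Uninduced cells correlated with ES at 0.934 and astrocytes at 0.915. Spheres had 1714 probe sets at least 2-fold higher and 621 lower than ES, of which 347 and 15 passed 4-fold. With arrays centred on their medians over the probe sets that enter, a shift by construction, the lower count was 1003. With quantile normalisation both counts stayed within the limit set for a change, so the size of the imbalance depends on the centring chosen. Relative to ES, uninduced cells had 2522 higher and 1650 lower, and astrocytes 3018 and 2662. Against astrocytes, spheres had 2795 higher and 2306 lower probe sets. Of 1392 probe sets at least 4-fold apart between ES and astrocytes, 49.9% (95% Wilson interval 47.3 to 52.6%) lay nearer to ES in uninduced cells and 84.1% (82.0 to 85.9%) in spheres. For the 517 higher in ES the shares were 32.3% and 94.8%, and for the 875 higher in astrocytes 60.3% and 77.7%. Selecting probe sets at 2-fold lowered the share of spheres to 71.6%.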

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

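The tests of residual MEF RNA, detection floor, slides and ES RNA in the spheres were chosen after the results were seen. The others were written first.

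In 8 of the list genes picked by the naming rule, the PM2i-iPSC array lay at least 2-fold on one side of ES and OM2i-iPSC at least 2-fold on the other. The difference was not tested, and over all 19315 genes compared, 248 were opposite. As log2 differences from ES, in the order PM2i-iPSC and OM2i-iPSC, they were 1.07 and -1.19 for Cdkn1c, -1.07 and 1.31 for Dusp4, -1.40 and 1.05 for Gad1, -1.39 and 1.08 for Hoxa2, -1.12 and 2.18 for Hoxc5, -1.19 and 1.04 for Ifi35, -1.53 and 2.89 for Lef1, and -2.46 and 1.78 for Nefl. The PM2i-iPSC values of Hoxa2 and Nefl are bounds. Of the 4 genes with other probes, Gad1, Lef1 and Nefl kept both signs on their median and Dusp4 did not. Dim probes were not filtered out there, and PM2i-iPSC minus ES was only -0.46 for Gad1 and -0.19 for Lef1.

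Ddx3y, Eif2s3y, Uty, Meg3, Rian and Mirg were higher on the OM2i-iPSC array than on ES and PM2i-iPSC. Residual MEF RNA is argued against: the 6 genes lay at 34.9% to 357% of their MEF level, while 30 fibroblast genes abundant in MEF had a median of 8.40% (95% interval 1.08 to 10.4%), with Dcn at 0.198% and Lum at 0.0913%, although Fn1 (53.4%) and Tagln (44.9%) of the 30, and Col3a1 (90.0%) outside them, were as high as the pattern. These values are from the brightest probes, and Cdh11, at 317% on that probe, was far lower than in MEF on its other probes. A detection floor is also argued against, since the lowest of the 6 lay 3.93 log2 units above the highest floor, and so are fewer active X chromosomes in OM2i-iPSC, which would raise X-linked genes in PM2i-iPSC, where they were -0.12 relative to autosomes (95% interval -0.20 to -0.03). A sex difference of the starting MEF was tested only in that form, and other forms of it stay open. A difference in the clone of the starting MEF, and in Dlk1-Dio3 imprinting, stays open and was not tested, as does a difference between slides. Kdm5d, also Y-linked, lay at 0.394% of its MEF level on OM2i-iPSC, so it did not rise with Ddx3y, Eif2s3y and Uty.

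Sterol synthesis genes were lower on the OM2i-iPSC array than on PM2i-iPSC. Probe GC content and level did not account for it, since the median of 0.79 was 0.68 (95% interval 0.01 to 1.30) after their correction. On the other probes of 13 genes the median was 0.079 (95% interval -0.28 to 1.03), which leaves single faulty probes open. OM2i-iPSC minus ES, also across slides, had a median of -0.32 (95% interval -0.76 to 0.27), and PM2i-iPSC minus ES, within a slide, 0.22 (95% interval -0.06 to 0.64), so a slide difference stays open for part of the gap and both intervals include 0. The compound named in the labels and a difference in the starting cells remain untested biological explanations, which these arrays cannot tell apart.

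Bmi1 spheres lay between uninduced cells and ES. If ES RNA were mixed into the sphere sample, 1 share would account for both directions. The ES share was 73.7% from 304 probe sets high in ES and 60.6% from 388 high in uninduced cells, a gap of 13.1 points (95% interval 7.69 to 19.7), between the bounds set for and against mixing. The quartiles of these shares were wide, 51.9 to 91.3% and 29.8 to 83.2%. At least 4-fold above both arrays were 34 of 20621 probe sets in spheres. Outside the range of the other 2 arrays were 36 in spheres, against 433 in uninduced cells and 194 in ES. Probe sets 10582545 and 10582549, low in ES at 1.62 and 2.04, were not diluted, with 11.62 and 10.73 in uninduced cells and 11.46 and 10.99 in spheres. Array error is unknown here and these 2 were picked for their width, so a mixture and cells in an intermediate state cannot be told apart.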

How the results depend on the processing

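Of 270 alternative values of the 46 main results, 248 kept their side of the limits set for a change and 22 moved. None was marked as changing direction, but counts and shares have no sign and so could not be. A count that stayed within its limit could still differ from the main one. Without a filter on dim genes, 12315, 12862 and 13282 genes were at least 2-fold higher in ES, PM2i-iPSC and OM2i-iPSC than in MEF. That setting takes raw differences of dim genes, for which the main setting gives a bound or no fold. The log2 floor was -6.85 in MEF against -5.13, -4.59 and -4.60 in the others. The median over all genes rose from 0.17, 0.15 and 0.25 to 0.69, 0.78 and 0.88. These counts therefore mix differences in background with differences in expression. The share of genes nearer to ES in PM2i-iPSC was 89.3% with quantile normalisation, 89.4% with the mean over a gene's probes, 92.0% with normexp and 84.6% with genes selected at 2-fold. In OM2i-iPSC it was 84.0% with quantile normalisation, 86.4% with genes above background on both arrays, 87.4% with normexp and 80.7% at 2-fold, and the cause was not tested. With the Affymetrix filter at the 75th percentile, which admits fewer probe sets, 1616 were higher and 1146 lower in uninduced cells than in astrocytes, 732 higher in spheres than in uninduced cells and 1572 higher in spheres than in astrocytes. Relative to ES, 890 were higher and 398 lower in spheres, 1566 higher and 767 lower in uninduced cells, and 1602 lower in astrocytes. With arrays centred on their medians over the probe sets that enter, a shift by construction, 1003 were lower in spheres than in ES. At 2-fold selection the share of spheres nearer to ES was 71.6%, and the cause was not tested.

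Of 8163 alternative values of the 1047 differences of genes under the naming rule that are reported here, 5776 stayed, 2340 moved and 47 changed sign. The mean over a gene's probes in place of the brightest changed the sign in 46, as its construction allows where probes disagree. Log2 differences under that choice follow. For ES minus MEF: Cdh11 -3.43, Dab2 0.26, Gbx2 0.37, Mylip 0.048, Hoxa3 -0.30, Dazl 2.91 and Xist -0.79. For PM2i-iPSC minus MEF: Cdh11 -4.97, Gbx2 0.48, Top2a 1.61, Stat3 0.32, Mylip 0.33, Hoxa3 -1.66, Dazl 2.11 and Xist -0.78. For OM2i-iPSC minus MEF: Cdh11 -4.24, Dab2 0.38, Gbx2 0.21, Mbp -0.11, Mcm4 1.35, Top2a 1.32, Spry2 1.03, Dazl 1.58, Hk1 0.30, Xist -1.41, Meg3 0.17 and Rian 0.39. For PM2i-iPSC minus ES: Fn1 0.16, Cspg4 0.46, Tek -0.23, Flt1 0.32, Tet3 0.38 and Dnmt3a 0.75. For OM2i-iPSC minus ES: Disp1 -0.66, Cbx2 0.060, Sox7 -1.62, Ncam1 0.87 and Rsad2 0.59. For PM2i-iPSC minus OM2i-iPSC: Disp1 0.997, Sufu -0.048, Cbx2 -0.32, Ncam1 -0.094, Flt1 0.75, Spry2 -1.36, Rsad2 -0.42 and Dnmt3a 0.73. With normexp, Lifr in PM2i-iPSC minus OM2i-iPSC changed sign to -0.54, and the cause was not tested.

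No paired analysis was possible because each group has 1 array and no result comes from a test. The planned normexp on mean signals and the planned mean over the probe sets of a gene were not run. Between 63.4% and 72.8% of the spots were well above background, so genes under the floor have bounds only, and the floor was lower in MEF.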

Other observations

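The test of chromosome 8 on other probes was written before its result, after the medians of the chromosomes were seen.

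Glycolysis genes were within 2-fold of ES in 11 of 11 genes in PM2i-iPSC (median log2 difference -0.02, 95% interval -0.53 to 0.35, percentile 72.6) and lower in 2 of 12 in OM2i-iPSC (median log2 difference -0.05, 95% interval -0.74 to 0.26, percentile 75.7), with Hk2 3.54-fold lower. Neural stem cell genes were higher than ES in 6 of 17 and lower in none in OM2i-iPSC (median log2 difference 0.50, 95% interval -0.31 to 1.25, percentile 89.6), among them Prom1 (5.35-fold) and Msi1 (3.93-fold), and higher in 2 and lower in 1 of 18 in PM2i-iPSC (median log2 difference -0.02, 95% interval -0.45 to 0.63, percentile 50.4). Mesoderm genes relative to ES had 2 higher and 1 lower of 9 in OM2i-iPSC (median log2 difference 0.48, 95% interval -0.66 to 1.47, percentile 62.5), with Bmp4 5.52-fold lower. Insig1, a sterol-regulated inhibitor of SREBP processing, was at least 16.3-fold and at least 6.51-fold higher in PM2i-iPSC and OM2i-iPSC than in ES. DNA methylation genes were lower than ES in 4 of 11 in PM2i-iPSC (median log2 difference -0.41, 95% interval -1.07 to -0.05, percentile 8.85), with Mbd2 5.55-fold lower. Microglia and macrophage genes were higher than MEF in 4 and lower in 3 of 12 in ES (median log2 difference -0.12, 95% interval -1.22 to 2.66, percentile 21.2), with Tyrobp at least 67.0-fold lower.

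Kdm5d, a Y-linked gene, was well above background in MEF and dimly in ES, and not in OM2i-iPSC, where Ddx3y, Eif2s3y and Uty were. The 4 probes of Xist disagreed: the brightest was 6.11-fold higher in ES than in MEF, while 2 others were lower.

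Genes of chromosome 8, placed by the coordinates in the MEF file, had the highest median of 20 chromosomes in OM2i-iPSC minus ES, 0.21 above the autosomal median (850 genes, 95% interval 0.13 to 0.30), and the lowest in PM2i-iPSC minus OM2i-iPSC, at -0.16 (95% interval -0.25 to -0.11). After correction for GC content and level the first was 0.17 (95% interval 0.13 to 0.28). A hypothesis is that part of the OM2i-iPSC may carry an extra copy of chromosome 8, for which 3 copies against 2 would give 0.58 in every cell. On 367 other probes of 272 genes, corrected in the same way, chromosome 8 was again the highest of the 20, at 0.21 (95% interval 0.13 to 0.36). That interval takes the probes as independent although some share a gene, so it may be too narrow. Other chromosomes also had intervals off 0, such as chromosome 10 in OM2i-iPSC minus ES at -0.15 (95% interval -0.23 to -0.04) and chromosome 14 in ES minus MEF at 0.27 (95% interval 0.13 to 0.47), but on the other probes chromosome 10 was at -0.019 (95% interval -0.13 to 0.10), and in OM2i-iPSC minus ES only chromosome 8 had an interval off 0 there. The other probes were read on the same arrays, so this is no independent sample, and no DNA was measured here.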
